A study of Mus musculus with 2 samples.

How the data were processed

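Both libraries were made from sorted GFP-positive, lineage-negative mouse bone marrow cells with the Chromium Next GEM 3′ kit, 1 from WT and 1 from Phf6 KO cells. The deposited matrices hold UMI counts per gene and cell barcode, unnormalised, for barcodes already called as cells. The matrix headers name Cell Ranger 6.0.2, while the submitters' processing notes name Cell Ranger 3.0.1 and the GRCm38 build, and the annotation release is not given in the sources used here. Gene positions came from GENCODE M21, which held 32158 of the gene IDs in the matrices. The libraries totalled 131667969 UMIs (WT) and 120408100 UMIs (KO).

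Cells with fewer than 500 detected genes (51 WT and 32 KO barcodes) or more than 10% mitochondrial UMIs (553 and 314) were left out, which left 4702 WT and 4930 KO cells. Doublets were scored with Scrublet as carried by scanpy, and the highest scores, 0.8% of barcodes per 1000 barcodes in the library, were removed: 224 WT and 221 KO cells. Scrublet's own threshold marked 5 WT and 89 KO cells and was not used. The 4478 WT and 4709 KO cells kept held 118834279 and 110416265 UMIs. Mitochondrial genes took 2.72% and 2.99% of these UMIs and ribosomal protein genes 27.6% and 26.7%.

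Both libraries were clustered together without integration: 2000 variable genes chosen within libraries, leaving out mitochondrial, ribosomal protein, sex-linked and haemoglobin genes, then 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 1. A cluster took the name of a class when the median log2 fold of the class's markers against other cells was at least 1, at least 3 markers were detected in at least 25% of its cells, and its top 10 genes held no more markers of another class than of its own. Clusters of low UMI count without an own marker among the top genes were also left unnamed. Names end in "like" because they rest on RNA alone.

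UMIs were summed over the cells of a library, and the log2 ratio of counts per 1000000 UMIs (CPM), KO over WT, was given with an exact conditional binomial interval. Levels of single libraries have exact Poisson intervals and shares of cells exact Clopper-Pearson intervals, and a share of 0 has a limit of 3 cells of the total. No p-value was computed, because cells of 1 library are not replicates. For each gene list, the median log2 ratio of members with at least 10 CPM was placed among 10000 random lists of the same size matched on expression, which describes these libraries and is no test across mice. A member was counted as higher or lower at 1.5-fold. The random range is the central 95% of those lists. Cell cycle phases were called after each cell was thinned to 5000 UMIs, which left out 242 WT and 199 KO cells of lower depth.

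The cell filters, the classes and their markers, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Phf6 and Runx1, and the 12 highest and 12 lowest log2 ratios over all cells at 50 CPM or more, leaving out mitochondrial, ribosomal protein, haemoglobin, sex-linked, immunoglobulin and T cell receptor genes and predicted models. It also named up to 4 members of each list by size of the log2 ratio, and the 6 highest and 6 lowest genes at 100 CPM or more in each class with at least 200 cells in each library. Not every gene so picked is described. Gene lists were compared in the same classes.

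The alternatives were a filter of 1000 genes and 5% mitochondrial UMIs, doublets kept, scaling by edgeR TMM factors or by a median of ratios, a mean per cell of UMIs per 10000, classes weighted alike, list members at 50 CPM or without a minimum, resolutions 0.5 and 2, Seurat CCA integration, classes by marker score per cell, and unthinned phases. Chosen after seeing the data were clusters weighted alike, clustering with the 1710 variable genes left after 290 genes that differ by 1.5-fold between the libraries were left out, and each alternative applied within classes.

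The ratios and list ranks were tested on simulated data with 8167 genes and 200 changed genes. The intervals held the true ratio for 94% to 100% of changed genes, by size of change, and for 95.2% of unchanged genes. Of 100 lists of randomly picked genes without a change, 5 lay outside the random range. The simulated counts held counting error alone. They check the calculation, and not how often an unchanged list of genes expressed together would leave the range. Reads of the vector and sequence variants were not analysed here.

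Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and Seurat 5.3.0.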

Results

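Single-cell RNA profiles were collected from mouse bone marrow cells that carried a truncated RUNX1 mutant found in myeloid leukaemia, in a Phf6 wild-type (WT) or Phf6 knockout (KO) background. Phf6 encodes a PHD-finger chromatin protein that is itself mutated in leukaemia. The cells had been transduced with a vector for the RUNX1 mutant and GFP, and were transplanted into recipient mice. GFP-positive, lineage-negative progenitors were sorted from recipient marrow 8 weeks after transplant. The design holds 1 WT library and 1 KO library, with 5287 and 5260 cell barcodes and 131667969 and 120408100 unique molecular identifiers (UMIs, counted RNA molecules). After filtering, 4478 WT cells with a median of 24800 UMIs and 4709 KO cells with a median of 21428 UMIs were compared. Intervals are exact 95% binomial or Poisson intervals and cover counting error only, since a single library per genotype gives no error between mice.

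The first question was whether Phf6 RNA was lower in the KO library. Phf6 (ENSMUSG00000025626, GRCm38 chromosome X, 52912266 to 52956943, plus strand) stood at 41.7 counts per 1000000 UMIs (CPM, interval 40.6 to 42.9) in WT cells and 20.7 (19.8 to 21.5) in KO cells. The log2 ratio of KO over WT was -1.01 (interval -1.09 to -0.94), from 4960 and 2282 UMIs. Phf6 was lower in the KO library in 19 of the 20 clusters with at least 50 cells per library. The exception was cluster 22, of basophil or mast cell-like cells, with 63 and 50 Phf6 UMIs and a log2 ratio of 0.04 (-0.53 to 0.60). Within classes the log2 ratio was -0.73 in HSC/MPP-like cells, -1.15 in neutrophil progenitor-like cells, -1.27 in monocyte-like cells and -1.28 in megakaryocyte-like cells. The sources used here do not say which part of the gene is deleted, and a 3′ tag outside that part checks nothing about the protein.

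Runx1 (ENSMUSG00000022952, GRCm38 chromosome 16, 92601466 to 92826149, minus strand), the gene of the introduced mutant, stood at 912 CPM in WT cells and 1188 in KO cells. Its log2 ratio was 0.38 (0.37 to 0.39). Reads of the vector were not analysed here, so native and introduced Runx1 are not separated. Xist, the X-inactivation RNA, was at 857 and 866 CPM.

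The next comparison asked how the classes of progenitors were shared out in each library. Cells that resemble haematopoietic stem and multipotent progenitors (HSC/MPP-like), with Angpt1 and Adgrl4 among the top genes of each of their 3 clusters, made up 16.3% of WT cells (interval 15.2 to 17.4) and 25.9% of KO cells (24.6 to 27.2). Cluster 1, with Cpa3 and Tox among its top genes, took 6.50% of WT and 14.2% of KO cells, while clusters 0 and 2, with the stem cell genes Hlf and Mecom, took 4.85% and 4.29%, and 4.94% and 7.37%. Erythroid-like cells, with Car1, Klf1 and Ermap, made up 5.58% of WT cells (4.93 to 6.30) and 1.83% of KO cells (1.46 to 2.25). Neutrophil progenitor-like cells, with Mpo, Elane and Ctsg, made up 27.6% of WT cells (26.3 to 28.9) and 24.6% of KO cells (23.3 to 25.8).

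Monocyte-like cells, with F13a1, Ly6c2 and Irf8, made up 13.3% of WT cells (12.3 to 14.3) and 15.6% of KO cells (14.6 to 16.7). Megakaryocyte-like cells, with Pf4 and Itga2b, were 14.4% of WT cells (13.3 to 15.4) and 12.9% of KO cells (11.97 to 13.9), intervals that overlap. The interval of their KO minus WT difference was -2.85 to -0.0443 percentage points. With doublets kept, at resolution 2 and after integration it included 0. The intervals also overlapped for basophil or mast cell-like cells (2.64% of WT, 2.17% of KO), dendritic cell-like cells (1.90% and 1.44%) and B cell-like cells (67 of 4478 WT and 50 of 4709 KO cells). The dendritic cell-like cluster also had the T or NK cell genes Klrd1, Klrk1 and Il7r among its top genes, and at finer clustering dendritic cell-like cells (75 WT, 82 KO) stood apart from T or NK cell-like cells (24 WT, 16 KO). Of the clusters left unnamed, cluster 13, with Apoe, Ms4a2 and Gata2, took 5.14% of WT and 3.65% of KO cells. Cluster 23, with the plasma cell genes Jchain and Mzb1, held 53 WT cells (1.18%) and 0 of 4709 KO cells, which allows a KO share of up to 0.0637% by a limit of 3 cells.

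The removal of likely doublets bears on cluster 23: barcodes with at least 50 Jchain UMIs numbered 59 in WT and 7 in KO, and removal left 50 and 0 of them. With doublets kept, the matching cluster held 62 WT and 7 KO cells. The HSC/MPP-like difference of 9.61 percentage points was 3.61 with the libraries integrated and 3.99 at finer clustering. Cluster 1 passed the naming minimum of 1 with a marker score of 1.13, and clusters with Cpa3, Angpt1 and Sox6 on top stayed under it, unnamed, at finer clustering (146 WT, 389 KO cells) and after integration (207 WT, 316 KO cells). Over 7 alternatives the KO minus WT difference ran from -4.94 to -3.05 points for erythroid-like cells, from -5.01 to -1.24 for neutrophil progenitor-like cells and from 1.13 to 2.51 for monocyte-like cells. The Newcombe interval of the difference included 0 for neutrophil progenitor-like cells with the stricter cell filter (-2.92 to 0.438). It also did so for monocyte-like cells with the libraries integrated (-0.157 to 2.47). For basophil or mast cell-like cells the difference was -0.469 (-1.11 to 0.158) in the main setting. Over the 7 alternatives that difference ran from -3.38 to -0.667, and its interval lay below 0 in each.

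**Figure D1:**
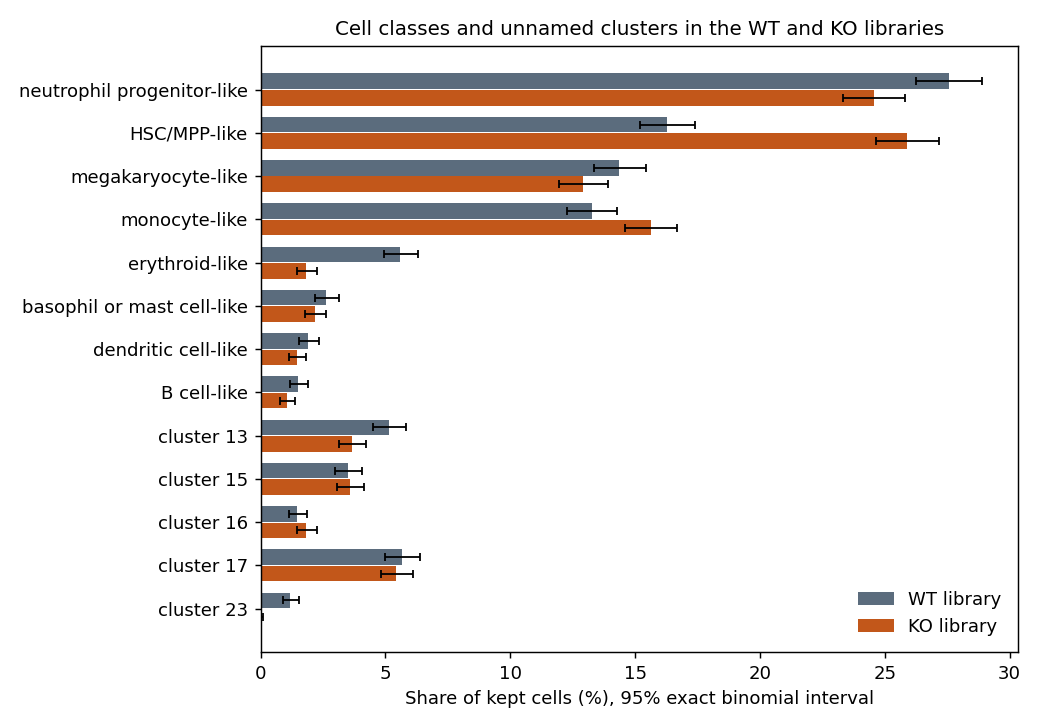
Share of kept cells in percent (horizontal axis) for each class or unnamed cluster in the WT library (grey) and the KO library (orange), with exact 95% binomial intervals as bars. HSC/MPP-like cells stand at 16.3% in WT and 25.9% in KO, and erythroid-like cells at 5.58% and 1.83%.

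Genes were ranked at a mean of at least 50 CPM over all cells and 100 CPM within classes, leaving out haemoglobin, sex-linked and some other families. Over all cells, the genes so ranked highest in the KO library included products of maturing neutrophils. Lcn2, which encodes the iron-siderophore binding protein lipocalin-2, stood at 53.3 CPM in WT and 143 in KO (log2 ratio 1.43, interval 1.38 to 1.47). Camp, the cathelicidin precursor, stood at 52.4 and 116 (1.14). Hp (haptoglobin) had a log2 ratio of 0.98 and Chil3, a chitinase-like protein of myeloid cells, 0.95. Neutrophil progenitor-like cells held 6066 of 6230 WT and 12612 of 12773 KO Camp UMIs. They held 2346 of 10458 WT and 6024 of 18733 KO Chil3 UMIs. Monocyte-like cells held 2460 of 6333 WT and 6287 of 15810 KO Lcn2 UMIs. Other genes ranked highest were the TGF-beta receptor gene Tgfbr1 (1.06), the interferon-induced genes Ifi27l2a (1.02) and Ifitm1 (0.99), the kinase gene Camk2d (1.03) and the transcription factor gene Pou2f2 (0.99). Mir99ahg, a noncoding RNA, was at 1.30, Ms4a4c at 1.13 and Nxph1 at 0.96.

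The genes ranked lowest in the KO library were led by Jchain, the joining chain of secreted antibodies, at 741 CPM in WT and 1.15 in KO (log2 ratio -9.33). Prg2, the eosinophil major basic protein gene, stood at 336 and 36.5 (-3.20). Then came genes of red cell precursors: the carbonic anhydrase genes Car1 (-1.46) and Car2 (-0.92), the haem synthesis genes Cpox (-1.14) and Alad (-0.68), the biliverdin reductase gene Blvrb (-1.05) and the peroxiredoxin gene Prdx2 (-0.96). Chchd10 was at -0.77, Hmgb3 at -0.69 and the tetraspanin gene Cd63 at -0.67. Of the 24 genes at both ends, 12 differed by over 2-fold.

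A few cells carried most of the Jchain and Prg2 UMIs. In kept cells with fewer than 50 UMIs of the gene, Jchain stood at 12.9 CPM in WT and 1.15 in KO, and Prg2 at 15.2 and 6.39. Barcodes with at least 50 Prg2 UMIs numbered 41 in WT and 15 in KO, of which removal of likely doublets left 34 and 2. With doublets kept, the log2 ratio was -3.22 for Jchain and -0.85 for Prg2. With clusters weighted alike, an alternative chosen after seeing the data, the ratio was -0.00 for Car1, -0.21 for Cpox, -0.24 for Blvrb, -0.27 for Car2 and -0.48 for Prdx2, against -0.65 for Cd63, 1.39 for Lcn2 and 0.92 for Tgfbr1. Nxph1 was 0.46 with classes weighted alike, Ifitm1 0.54 as a mean per cell and Camp 0.73 with doublets kept.

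**Figure D2:**
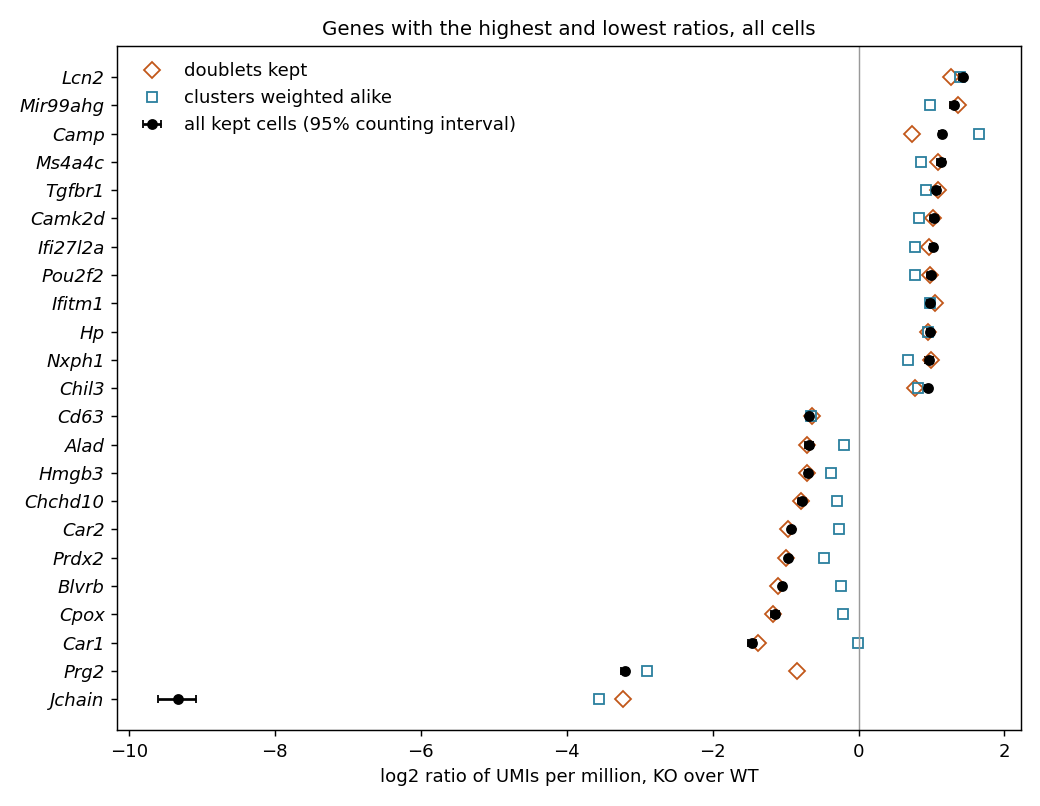
Log2 ratio of CPM, KO over WT (horizontal axis), of genes with the highest and lowest ratios over all kept cells (black points with 95% counting intervals), with doublets kept (orange diamonds) and with clusters weighted alike (blue squares). Car1 moves from -1.46 to -0.00 when clusters are weighted alike, while Lcn2 stays between 1.27 and 1.43.

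Interferon response genes were higher in the KO library as a group: 16 of the 25 measured members were at least 1.5-fold higher, 0 were as much lower, and the median log2 ratio was 0.80. Iigp1, an interferon-induced GTPase gene, stood at 4.74 CPM in WT and 28.5 in KO (2.59). Ifi204 (1.21), the antiviral gene Oasl2 (1.13) and Rtp4 (1.05) were also higher. The list median lay above the median of all genes in 19 of 20 clusters. It was lowest in cluster 15, a low-UMI cluster with Tubb1 and Gp6, at -0.18, and highest in cluster 2, of HSC/MPP-like cells, at 1.15. At finer clustering, a monocyte-like cluster with Cxcl10, Isg15 and Ifit1 on top held 2 WT and 29 KO cells. Genes of MHC class I presentation had a median of 0.33, with 1 of 11 members at least 1.5-fold higher: Nlrc5, a transactivator of these genes (0.78).

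Secondary and tertiary granule genes, expressed late in neutrophil maturation, had a median log2 ratio of 0.73, with 5 of 10 members at least 1.5-fold higher, led by Ngp (2.23). Primary granule genes, expressed earlier, had a median of 0.03, and Elane (-0.44) and Lyz2 (0.37) lay on opposite sides. Lymphoid priming genes had a median of 0.46, with 3 of 8 members higher: Dntt, the terminal transferase gene (1.90), the receptor gene Flt3 (0.89) and the chromatin organiser gene Satb1 (0.84). Cytokine and growth factor receptor genes had a median of 0.41, with 6 of 20 members higher and 1 lower. Csf2rb2 (1.18), Tgfbr1 (1.06) and Flt3 (0.89) were among the highest.

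Haemoglobin genes stood at 1643 CPM in WT and 351 in KO, and all 4 were lower (median log2 ratio -2.28). Erythroid genes had a median of -0.92, with 11 of 14 members at least 1.5-fold lower, among them the erythroid transcription factor gene Klf1 (-1.62) and Ermap, an erythroblast membrane protein gene (-1.41). Myc target genes had a median of -0.36, led by the polyamine enzyme gene Odc1 (-0.64) and the chaperonin gene Hspd1 (-0.53). Ribosome biogenesis genes had a median of -0.23, with Dkc1 at -0.43 and Ncl at -0.36, and 0 of 25 members differed by 1.5-fold. G1/S genes had a median of -0.14 and G2/M genes of -0.09.

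Subunits of the complexes that bind PHF6 had a median log2 ratio of -0.01, p53 target genes 0.01, DNA repair genes -0.01 and chromatin regulators mutated in myeloid leukaemia 0.05. None of these 4 lists lay outside the central 95% of random lists of matched expression. Of the 34 lists so tested, 14 lay above that range, 6 below and 14 within it, while the median of all genes was 0.06. The erythroid and G2/M calls ended with classes or clusters weighted alike (erythroid median -0.00 with clusters weighted alike, haemoglobin -0.87, cytokine receptors 0.20), and the lymphoid priming call ended with a mean per cell (median 0.20).

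**Figure D3:**
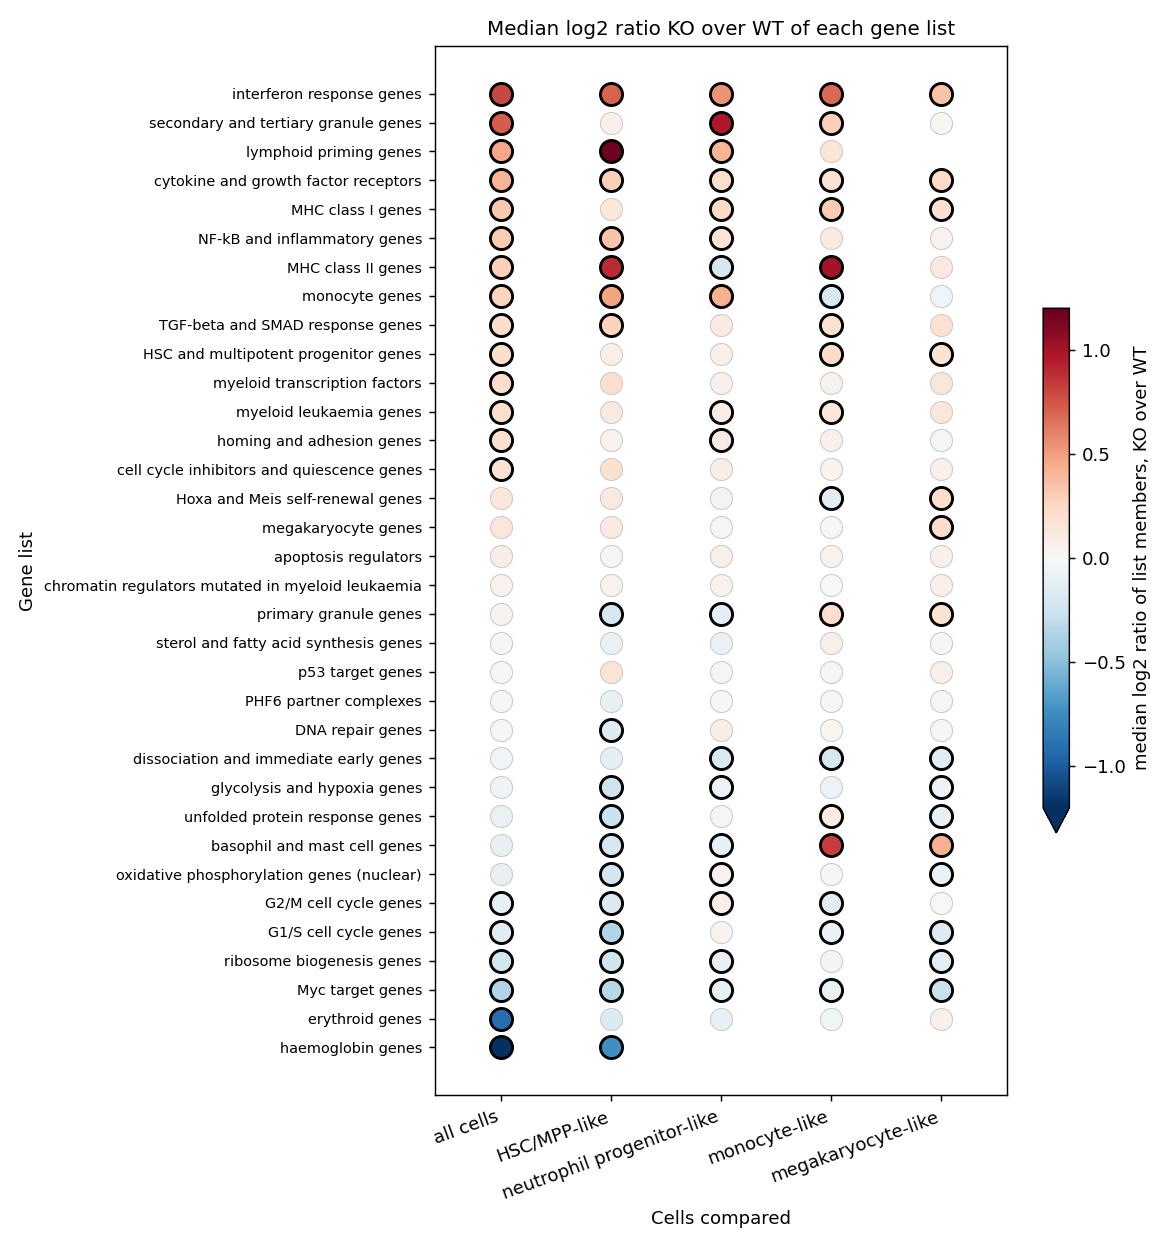
Median log2 ratio KO over WT (colour) of each gene list (vertical axis) in all cells and in the 4 classes with at least 200 cells per library (horizontal axis), with black rings where the median lies outside the central 95% of matched random lists. Interferon response genes are ringed in each of the columns, with medians from 0.35 to 0.80.

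HSC/MPP-like cells of the KO library (1219 cells, against 729 in WT) had more RNA of lymphoid priming genes. Their median log2 ratio was 1.18 and 4 of 6 measured members were at least 1.5-fold higher: Dntt (23.3 CPM in WT, 65.7 in KO), Satb1 (1.31), Lsp1 (1.23) and Flt3 (1.13). The class was made up differently in the libraries, with 291 WT and 670 KO cells in cluster 1, and the lymphoid priming median was 0.51 within cluster 0, 0.98 within cluster 1 and 1.15 within cluster 2. Scored cell by cell with markers, lymphoid progenitor-like cells were 3.46% of WT and 7.37% of KO cells. Those markers include Dntt, Flt3 and Satb1 of the same list, so these shares are no separate support. MHC class II genes had a median of 0.90, with 4 of 6 higher, led by the invariant chain gene Cd74 (21.9 and 79.5 CPM, 1.86) and H2-Eb1 (1.33). Interferon response genes had a median of 0.71, with 15 of 26 higher, led by Iigp1 (1.75) and Ifit1 (1.59). Among genes at 100 CPM or more, the highest in HSC/MPP-like cells were Tox, a transcription factor gene of lymphocyte development (51.3 and 153 CPM, 1.58), Ifitm1 (2.83-fold), Abhd17b (1.16), Parp8 (0.97), the kinase gene Pim1 (0.87) and the homeobox gene Pbx3 (0.86).

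The lowest at 100 CPM or more in these cells were the apolipoprotein gene Apoe (161 and 53.4 CPM, log2 ratio -1.60), the calcium-binding protein gene S100a6 (-1.32), Cacnb2 (-0.94), Cd63 (-0.73), Nrgn (-0.62) and the histone chaperone gene Nasp (-0.58). Several list medians lay below the random range with few members at least 1.5-fold lower. The median was -0.36 for G1/S genes, with 2 of 42 members lower (Mcm2 -0.60), and -0.18 for G2/M genes, with 4 of 33 lower. Within clusters 0, 1 and 2 the G1/S median was -0.45, -0.32 and -0.32, and the G2/M median -0.18, -0.20 and -0.22. Myc targets had a median of -0.34, with 0 of 21 lower by 1.5-fold (Nme1 -0.52), and unfolded protein response genes -0.27, with 1 of 14 lower (Sdf2l1 -0.64). Glycolysis genes had a median of -0.24 (Eno1 -0.48), ribosome biogenesis genes -0.24 and oxidative phosphorylation genes -0.22, with 0 of 18, 0 of 25 and 0 of 27 members lower by 1.5-fold. Of the monocyte genes, 3 of 6 were higher (median 0.48), led by the transcription factor gene Irf8 (1.24).

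Of 34 lists, 7 lay above the random range in HSC/MPP-like cells and 11 below. The monocyte gene call ended with the libraries integrated and when genes that differ were left out of the clustering, whereas the lymphoid priming, MHC class II, interferon, G1/S and Myc calls held in all 6 alternatives. The interferon median was 0.41 at finer clustering.

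In neutrophil progenitor-like cells (1234 WT, 1157 KO), granule genes of later maturation were higher in the KO library. Secondary and tertiary granule genes had a median log2 ratio of 0.97 and 8 of 12 were at least 1.5-fold higher, among them the lactoferrin gene Ltf (2.32), Ngp (2.19), Chil3 (1.40), Lcn2 (90.7 and 237 CPM, 1.39) and Camp (1.09). S100a9, a calprotectin subunit gene, stood at 2591 and 4681 CPM (0.85). The secondary and tertiary granule median was 1.43 within cluster 14, which has S100a8 and S100a9 on top and held 412 WT and 266 KO cells. It was 0.31 within cluster 11 (263 WT, 354 KO), 0.14 within cluster 12 and 0.02 within cluster 7. Scored cell by cell, maturing neutrophil-like cells were 24 in WT (0.536%) and 65 in KO (1.38%). The markers used, among them Ltf, Ngp, Lcn2 and Camp, are members of the same list, so these counts are no separate support. Elane, the neutrophil elastase gene of primary granules, was lower, at 6039 and 4020 (-0.59), and the primary granule list had a median of -0.12. Interferon response genes had a median of 0.54, with 7 of 15 higher, led by Ifi27l2a (1.64) and Isg15 (1.12).

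Monocyte genes were higher here too, with a median of 0.42 and 4 of 11 members at least 1.5-fold higher, led by the chemokine receptor gene Ccr2 (0.82) and the cathepsin gene Ctss (0.78). Cluster 11, with the monocyte gene F13a1 among its top genes, held 263 WT and 354 KO cells. For this list, the primary granule list and single genes of this class, the mix of clusters is not separated here from a change within them. Hp (0.81) and Ifitm3 (0.80) were also among the highest genes at 100 CPM or more. The lowest at that level were Prg2 (-3.33), the ubiquitin ligase gene Nedd4 (-0.98), Cd63 (-0.93), Angpt1 (-0.64), Elane and Prdx2 (-0.42). Cells with at least 50 Prg2 UMIs held 95.5% of the Prg2 UMIs of all kept WT cells and 82.5% of those of KO cells, and 23 WT and 2 KO cells of that kind lie in cluster 12 of this class. Another 11 WT and 0 KO such cells lie outside this class, in cluster 23, which has Jchain, Mzb1 and Prg2 among its top genes. Scored cell by cell with markers that include Prg2, eosinophil-like cells were 98 in WT (2.19%) and 41 in KO (0.871%). The stricter cell filter gave an unnamed cluster with Prg2 and Prg3 on top, of 112 WT and 18 KO cells. Dissociation and immediate early genes, a list that includes heat shock genes, had a median of -0.19. Of its 19 members 1 was at least 1.5-fold lower, with the transcription factor gene Egr1 at -0.91. Myc targets had a median of -0.10, with 1 of 21 lower, the cyclin gene Ccnd2 at -0.86.

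Of 33 lists, 11 lay above and 7 below the random range in these cells. The monocyte gene call ended at coarser clustering (median 0.08), the primary granule call without the differing genes and the Myc call with the stricter cell filter. Over 6 alternatives Prg2 ran from -3.31 to 0.16, Cd63 from -0.88 to -0.36, Elane from -0.63 to -0.29, Angpt1 from -1.41 to -0.36 and S100a9 from 0.76 to 1.36.

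Monocyte-like cells (594 WT, 736 KO) had higher interferon response genes in the KO library, with a median log2 ratio of 0.69 and 14 of 23 members at least 1.5-fold higher. Iigp1 stood at 0.998 CPM in WT and 25.1 in KO (4.65), Usp18 at 1.82 and Isg15, a ubiquitin-like modifier gene, at 1.68. MHC class I genes had a median of 0.30, with Nlrc5 at 1.00. The monocyte list had a median of -0.19, with 2 of 14 members at least 1.5-fold lower and 5 of 14 above the median of all genes: the fractalkine receptor gene Cx3cr1 was at -0.90, the fibronectin gene Fn1 at -0.88 (206 and 112 CPM) and Ly6c2 at -0.43.

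At 100 CPM or more, the highest genes in monocyte-like cells were S100a8 (125 and 309 CPM, log2 ratio 1.31), Camk2d (62.4 and 152), Lcn2 (1.04), Pbx3 (0.80), Hp (0.76) and the adaptor gene Fyb (0.75). The lowest at that level, beside Fn1, were Hist1h2ac (-0.84), the phospholipase gene Plcb1 (-0.82), the heat shock genes Hspa1b (-0.63) and Hspa1a (-0.60), and App (-0.61). Dissociation and immediate early genes had a median of -0.21, with 4 of 21 members at least 1.5-fold lower, among them Hspa1b, Hspa1a and Egr1 (-1.02). MHC class II genes had a median of 1.01, with 4 of 6 higher, led by H2-Aa (1.41), but the median was -0.16 when genes that differ were left out of the clustering. S100a8 was at 0.05 with doublets kept and 0.13 without the differing genes. Of 33 lists, 11 lay above and 6 below the random range.

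In megakaryocyte-like cells (643 WT, 608 KO), interferon response genes had a median log2 ratio of 0.35, with 6 of 21 members at least 1.5-fold higher, among them the GTPase gene Igtp (0.66). Megakaryocyte genes had a median of 0.22, with 2 of 11 higher, among them the platelet chemokine gene Ppbp (614 and 959 CPM, 0.64). Chchd7, which encodes a mitochondrial coiled-coil-helix protein, was the highest gene at 100 CPM or more (73.7 and 187, 1.35), and Serpina3b (0.80), the Mediator kinase gene Cdk8 (0.71) and Pbx3 (0.66) were also among the highest.

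Apoe (-0.92) and Cd63 (-0.73) were the lowest in megakaryocyte-like cells among ranked genes at 100 CPM or more, before the antiproliferative gene Btg2 (-0.54), the chaperone genes Hsp90ab1 (-0.52) and Clu (-0.52), and Prdx2 (-0.50). Myc targets had a median of -0.26 (0 of 21 members at least 1.5-fold lower), G1/S genes -0.17 (0 of 42), dissociation and immediate early genes -0.15 (1 of 19) and ribosome biogenesis genes -0.12 (0 of 25). Of 32 lists, 8 lay above and 7 below the random range, and 3 lay above it with the stricter cell filter.

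Cell cycle phase was called from G1/S and G2/M genes in cells thinned to 5000 UMIs. G1 calls were 39.1% of WT cells (37.6 to 40.6) and 46.7% of KO cells (45.3 to 48.2), S calls 32.9% and 29.6%, and G2/M calls 28.0% and 23.7%. In HSC/MPP-like cells G1 calls were 66.9% (63.3 to 70.3) and 77.6% (75.2 to 80.0), and S calls 29.6% and 19.6%. Cluster 17 (253 WT, 256 KO cells), with Top2a and Mki67 among its top genes, scored best for HSC/MPP but stayed unnamed at 0.754. The phase shares and the G1/S and G2/M medians of HSC/MPP-like cells leave out the cells of cluster 17. In thinned cells the intervals overlapped for each phase in neutrophil progenitor-like, monocyte-like and megakaryocyte-like cells. Erythroid-like G1 calls were 0.412% of 243 WT cells (0.0104 to 2.27) and 9.41% of 85 KO cells (4.15 to 17.7). Without thinning, megakaryocyte-like G1 calls were 60.7% (56.8 to 64.45) and 68.8% (64.9 to 72.4), intervals that do not overlap. With doublets kept, neutrophil progenitor-like S calls were 43.7% (40.3 to 47.0) and 51.5% (47.9 to 55.1), also without overlap. Free RNA enters such calls and was not removed, so they are not read as a rate of cycling.

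**Figure D4:**
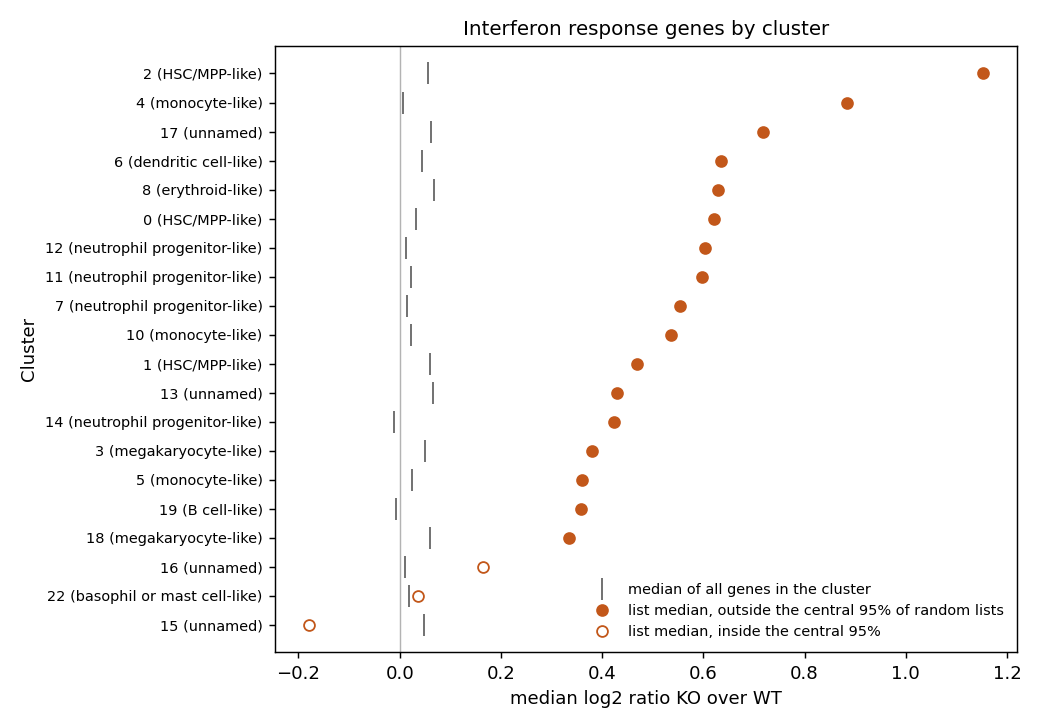
Median log2 ratio KO over WT (horizontal axis) of the interferon response genes in each cluster with at least 50 cells per library (vertical axis), filled where it lies outside the central 95% of random lists, with grey ticks for the median of all genes in the cluster. The list median runs from -0.18 in cluster 15 to 1.15 in cluster 2 and lies outside that range in 17 of 20 clusters.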

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

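The pairing of classes was chosen only after the results were seen, and none of the differences between classes was tested. In 5 gene lists the median log2 ratio of KO over WT lay above the random range in 1 class and below it in another, by at least 0.1 from 0 on each side. With a median under 0.1 on the higher side, so did G2/M genes (0.07 in neutrophil progenitor-like and -0.18 in HSC/MPP-like cells), oxidative phosphorylation genes (0.05 and -0.22 in the same classes) and unfolded protein response genes (0.0952 in monocyte-like and -0.27 in HSC/MPP-like cells). Monocyte genes were at 0.48 in HSC/MPP-like cells, with Irf8 at 1.24, and at -0.19 in monocyte-like cells, with Cx3cr1 at -0.90, and these calls held in 4 of 6 and 6 of 6 alternatives. MHC class II genes were at 1.01 in monocyte-like cells and at -0.20 in neutrophil progenitor-like cells, where 3 members were measured, and the calls held in 5 of 6 and 4 of 6. Primary granule genes were at 0.21 in monocyte-like cells, led by Ms4a3 (0.70), and at -0.21 in HSC/MPP-like cells, where Elane was at -0.59 and Mpo at 0.66, and the calls held in 5 of 6 and 2 of 6. Basophil and mast cell genes were at 0.83 in monocyte-like cells, with 3 members measured, and at -0.21 in HSC/MPP-like cells, where Ms4a2 was at -1.72, and the calls held in 3 of 4 and 2 of 6. Hoxa and Meis self-renewal genes were at 0.21 in megakaryocyte-like cells and at -0.13 in monocyte-like cells, although Pbx3 was higher in both (0.66 and 0.80), and the calls held in 4 of 6 and 3 of 6.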

How the results depend on the processing

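Clusters weighted alike, clustering without the genes that differ, and all alternatives within classes were chosen only after the results were seen. Of the values that answer a comparison, 146 stayed within their counting interval or within 1.5 times a count, and 22 moved. Of the other values, 930 stayed, 621 moved in size and 9 reversed; the cause was not tested for any that moved or reversed. The HSC/MPP-like difference of 9.61 points was 7.90 with the stricter cell filter, 3.99 at resolution 2, 3.61 after integration and 7.85 without the differing genes. The basophil or mast cell-like difference was -1.35 with the stricter filter, -1.11 at resolution 2 and -3.38 by marker score, which also put dendritic cell-like cells at 0.518. Erythroid-like cells were at -4.94 with doublets kept and neutrophil progenitor-like cells at -5.01 without the differing genes. Phf6 was at -0.87 as a mean per cell. Of the 24 genes named over all cells, 12 were also named with a mean per cell, 12 with classes weighted alike and 11 with clusters weighted alike. Lists above the random range fell in number from 14 to 9 under either weighting, and those below numbered 10 with a mean per cell. The G2/M list over all cells reversed to 0.0027 with classes and 0.0022 with clusters weighted alike. Within classes, 6 of 12 named genes were also named in HSC/MPP-like cells at resolution 2, 6 in neutrophil progenitor-like cells at resolution 0.5 and 7 in monocyte-like cells at resolution 0.5. In neutrophil progenitor-like cells Prg2 reversed to 0.16 at resolution 0.5, basophil and mast cell genes to 0.35 with the stricter filter and 0.0017 at resolution 2, and leukaemia genes to -0.13 at resolution 0.5 and -0.11 without the differing genes. In monocyte-like cells Hoxa and Meis genes reversed to 0.14 at resolution 0.5 and MHC class II genes to -0.16 without the differing genes, and 5 lists lay above the random range with doublets kept. In megakaryocyte-like cells 3 lists lay above it with the stricter filter. Depth limits the small classes: 0 of 4709 kept KO cells in cluster 23 allows a share of up to 0.0637% by a limit of 3 cells, and with doublets kept the matching cluster held 7 KO cells.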

Other observations

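The tests of explanations were all chosen only after the results were seen. Haemoglobin genes did not move together in HSC/MPP-like cells: Hbb-bt was higher in the KO library (32.4 and 79.7 CPM, log2 ratio 1.30, interval 1.14 to 1.46), while Hba-a1 (-1.21) and Hbb-bs (-0.73) were lower. In neutrophil progenitor-like and monocyte-like cells the 1 haemoglobin gene measured was lower, at -1.35 and -0.79. In megakaryocyte-like cells 2 were measured, with a median of -1.60. Whether free RNA accounts for haemoglobin UMIs in these 4 classes was not tested. Receptor genes in HSC/MPP-like cells were higher for Csf2rb2 (1.36), Flt3 (1.13) and Tgfbr1 (0.90), and the cytokine signalling inhibitor gene Socs3 was at 1.05. Vcam1, an adhesion gene, was lower in neutrophil progenitor-like cells (79.0 and 28.2 CPM, -1.49). Jchain stood at 11.3 to 21.01 CPM across the 8 named classes in WT and at 0.464 to 6.198 in KO, and whether this is free RNA of the Jchain-high cells was not tested.

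Erythroid-like cells took a share 0.327 times as large in the KO library, or 0.579 times after integration (7.26% and 4.20%) and 0.457 times by marker score. The integrated class holds a cluster with Rhd and Ermap on top, of 190 WT and 63 KO cells, and one with Tgfbr3 and Apoe, of 135 and 135 (3.01% and 2.87%), so the difference there lies in the first. Loss of these cells to the filters used here is argued against by the deposited barcodes before those filters. Those with at least 0.5% of UMIs on erythroid genes were 203 of 5287 in WT (3.84%, interval 3.34 to 4.39) and 70 of 5260 in KO (1.33%, 1.04 to 1.68), a ratio of 0.347. The deposited barcodes had already been called as cells, so a loss at that step is not covered. For the class as a whole, cluster boundaries are argued against by the highest difference over all ways of making classes, -3.05 percentage points. With 1 library per genotype, an effect of Phf6 and a difference between the 2 libraries other than genotype cannot be told apart.

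Interferon response genes were higher in the KO library in most clusters. A larger share of clusters rich in interferon RNA is argued against by the list median of 0.71 with clusters weighted alike. A small set of interferon-high cells within clusters is argued against as the whole cause by a median of 0.70 once the 10% of cells highest in these UMIs were left out of each cluster in each library, while a broader shift within clusters stays open. Free RNA in the droplets is argued against by the 3 clusters of low UMI count, where KO exceeded WT by 389 CPM, against 530 in other clusters and 2203 if each droplet had gained the same number of UMIs. With 1 library per genotype, an effect of Phf6 and a difference between the 2 libraries other than genotype, such as a response in 1 set of recipients, cannot be told apart.

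Of 5046 genes compared, 5 were higher in the KO library by a log2 ratio of at least 0.3 in each of 20 clusters, and 0 were as much lower: Commd10 (27.0 and 72.0 CPM over all cells, 1.42), Gm49980 (1.54), Chchd7 (0.90), Pbx3 (0.87) and H2-T22 (0.71). They were picked after their values were seen. A chromosomal segment carried along with the Phf6 allele is argued against, as 0 of them lay within 10 Mb of Phf6 on chromosome X: they lie on chromosomes 18, 18, 4, 2 and 17. For the 5 genes, a strain variant against the reference, a difference between the 2 libraries other than genotype and an effect of Phf6 cannot be told apart. Each genotype has 1 library, and sequence variants were not analysed here.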
